A study of Mus musculus with 4 samples.

How the data were processed

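The series measured DNA copy number in cancer cells of mice that over-express the microRNA miR-125b. Genomic DNA was taken from 4 cancers of female C57Bl/6 mice, per the labels. There were 2 myeloid cancers, sorted as CD11b+ bone marrow cells, and 2 B cell cancers, sorted as CD19+ cells from bone marrow (B cell cancer 1) or as GFP+ CD19+ cells from spleen (B cell cancer 2). Each sample was hybridised on its own 2-colour NimbleGen comparative genomic hybridisation array, in which cancer DNA and reference DNA compete for the same probes. The cancer DNA carried Cy3 (read at 532 nm) and the DNA of a healthy wild type mouse carried Cy5 (read at 635 nm), per the labels and the file headers, with no dye swap among these arrays. Per the labels, both myeloid arrays and the array of B cell cancer 1 used the same reference DNA, and B cell cancer 2 used another.

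The deposited tables give log2 values per probe. Per the file headers, the authors deposited the log2 intensity of each channel, their difference, a version corrected for position on the array surface, and a version normalized after that correction, whose difference is the corrected log2 ratio of cancer over reference. The normalized channels had nearly equal quantiles on every array, with differences of at most 0.0040 log2 units, so the normalization brought both channels of an array to 1 distribution. The scanner, the software and the correction methods are not given in the sources used here. The deposited tables also give the GC content of each probe as a fraction, per the file headers. The deposited value tables of the series held the same corrected log2 ratios, with a largest difference of 0. The files used here hold probe values, and segments were computed from them as described below.

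The array design of myeloid cancers 1 and 2 and B cell cancer 1 had 713358 probes, with a median spacing of 3530 bp. The chromosome lengths written in those tables are those of the mouse build mm9, and positions of these 3 arrays are given in mm9. The design of B cell cancer 2 had 385079 probes with a median spacing of 5776 bp. On 5 of 22 chromosomes its probes lay beyond the end of the chromosome in mm9, so it follows another build, whose name is not given in the sources used here. No position was converted between the builds. The gene table used here was of the assembly GRCm38.p6, which matches neither design, and served only to place genes on chromosomes. Positions of genes in the builds of the arrays were not used here.

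Corrected log2 ratios were centred on the autosomal median of each array, with no further normalization. The medians before centring were 0.001 and 0.004 for myeloid cancers 1 and 2, and -0.016 and -0.032 for B cell cancers 1 and 2. The SD of single datapoints was 0.133, 0.149, 0.110 and 0.212 in that order, which together with the number of arrays limits the precision. The array of B cell cancer 1 had 40 saturated spots and that of B cell cancer 2 had 7.

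Per chromosome, the median of the datapoints was taken on each array. These medians were planned without a test, so the exact permutation test was not part of their plan. The limma fit over the 19 autosomes of all 4 arrays was added after the data were seen. Log2 ratios were also averaged in 100 kb bins with at least 3 datapoints. The bins were tested with limma (lmFit and eBayes) in a model with 1 mean per lineage. A bin was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute mean of at least 0.15. The plan had all 4 arrays in this fit. Because bins of B cell cancer 2 lie in another build, the fit used 3 arrays, and its B cell mean is the value of B cell cancer 1 alone, which is assumed to vary like the myeloid arrays. The fit had 1 residual degree of freedom per bin. Its prior degrees of freedom were estimated as infinite, so 1 spread was shared by all bins. The reference is 1 control sample, so a ratio tested against 0 leaves out the spread between control animals. The labels do not say in words that samples of 1 lineage came from separate animals, so the p-values measure only the spread between these samples.

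Segments were found per array and chromosome by penalised least squares (the PELT algorithm), with a penalty of 4 times the logarithm of the number of datapoints, at least 5 datapoints per segment and values limited to 3 SD. A segment was called at a mean of at least 0.25 from 0 and at least 10 datapoints. Adjacent segments of 1 direction past the threshold were joined before their datapoints were counted. The joining rule was chosen after the data were seen, since a loss on chromosome 13 had been split into parts that were too short. Called segments of 1 direction less than 500 kb apart are described as 1 region. The span of a region includes any uncalled gap in it. Its mean, SD and datapoints are those of its called segments alone. Segments of a pair of arrays were counted as shared at an overlap of 50% of the shorter, and set beside 1000 random shifts round the genome.

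The segment search was tested on simulated data with the noise of each array, over the autosomes other than chromosome 11. Segments of 10 datapoints with a size of 0.6 were found in 100% of cases in both myeloid arrays and in B cell cancer 1, and in 75% in B cell cancer 2. At a size of 0.3 the shares were 20%, 0%, 50% and 0%, in the order myeloid 1, myeloid 2, B cell 1 and B cell 2. With 50 datapoints and a size of 0.3 they were 100%, 95%, 100% and 90%, and no segment was called where none was planted. In a simulated myeloid comparison over 25632 bins, the bin test found 100% of bins changed by 0.3 and 100% of those changed by -0.6, and called 2 of 25432 unchanged bins. The simulated noise was drawn separately for each array, with no difference carried by the shared reference DNA. The rate of false calls in the real comparison is therefore not known from it.

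The rule for named regions was fixed before the data were examined. It takes, per array, the 5 called segments with the largest absolute mean among those of at least 20 datapoints and the 5 longest ones, and, per bin comparison, the 10 runs of adjacent called bins with the smallest adjusted p. Per array it was applied to regions rather than to single segments, so the longest spans can include uncalled gaps. It names genes only where an annotation of the build is used, so regions are named by chromosome and position. The focal loss on chromosome 13 of B cell cancer 2, its loss on chromosome 19 and the chromosome 4 interval of the myeloid cancers were named after their values were seen, as were segments of fewer than 10 datapoints. The gene lists were also fixed before and are reported only by chromosome. Planned locus values for Irf4, the antigen receptor loci, the gene lists and the miR-125b hairpins were not analysed here. Alternatives covered the bin size, the datapoint minimum, the centring, the size and segment thresholds, a running median, the overlap rule, left-out arrays and, added later, the ratio before correction and a GC correction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.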

Results

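DNA copy number was measured along the genome in 2 myeloid and 2 B cell cancers of mice over-expressing miR-125b, a microRNA whose overexpression drives leukemia. Each cancer was compared with healthy wild type DNA on its own array, and a log2 ratio above 0 marks more DNA in the cancer. A whole-cell change from 2 to 3 copies has a nominal log2 ratio of 0.58, and a change from 2 copies to 1 has a nominal ratio of -1. The arrays of myeloid cancers 1 and 2 and B cell cancer 1 carried 713358 probes. The array of B cell cancer 2 carried 385079, on another genome build. Group values are means ± SD over arrays. Values of a region in 1 array have no replicates and are given as mean ± SD over its datapoints.

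The first comparison asked whether the lineages differed in whole chromosomes. Chromosome 11 had a raised ratio along its whole length in both B cell cancers and in neither myeloid cancer. It is called a gain here, though for B cell cancer 2 a difference in the reference DNA was not excluded. Its median log2 ratio was 0.47 in B cell cancer 1 and 0.40 in B cell cancer 2, a mean of 0.43 ± 0.045 (SD, n = 2). In the myeloid cancers it was -0.011 and -0.032, a mean of -0.022 ± 0.015 (SD, n = 2). All 25 windows of 5 Mb along chromosome 11 exceeded 0.25 in both B cell cancers. The window medians ran from 0.42 to 0.53 in B cell cancer 1 and from 0.34 to 0.44 in B cell cancer 2. In the myeloid cancers 0 of 25 windows exceeded 0.25.

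The B cell minus myeloid difference on chromosome 11 was 0.45 ± 0.018 (SE), with an adjusted p of 1.70e-07 in the limma fit over 19 autosomes. That fit draws the spread of chromosome 11 toward the smaller spread of the other autosomes, so this SE and p are smaller than its own arrays give. Before the authors' correction the SE was 0.037 and the adjusted p in limma was 0.0019. Both B cell values lay above both myeloid values. A two-sided exact permutation test gave p = 0.333, the smallest that 2 against 2 arrays allow. All other autosome medians lay between -0.045 and 0.028 over the 4 arrays. Among them chromosome 4 also differed between the lineages, by -0.032 ± 0.0069 (SE), with an adjusted p of 0.0185 in the limma fit. On the B cell arrays the centring took in the raised chromosome 11, and the medians of the other autosomes were all at or below 0. They ran from -0.017 to 0 in B cell cancer 1 and from -0.045 to -0.003 in B cell cancer 2. An offset from the centring was not separated from the chromosome 4 difference. The myeloid mean of chromosome 4 was 0.023 ± 0.0071 and the B cell mean was -0.0085 ± 0.0021 (SD, n = 2 each). An exact permutation test gave p = 0.333 there too.

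**Figure D1:**
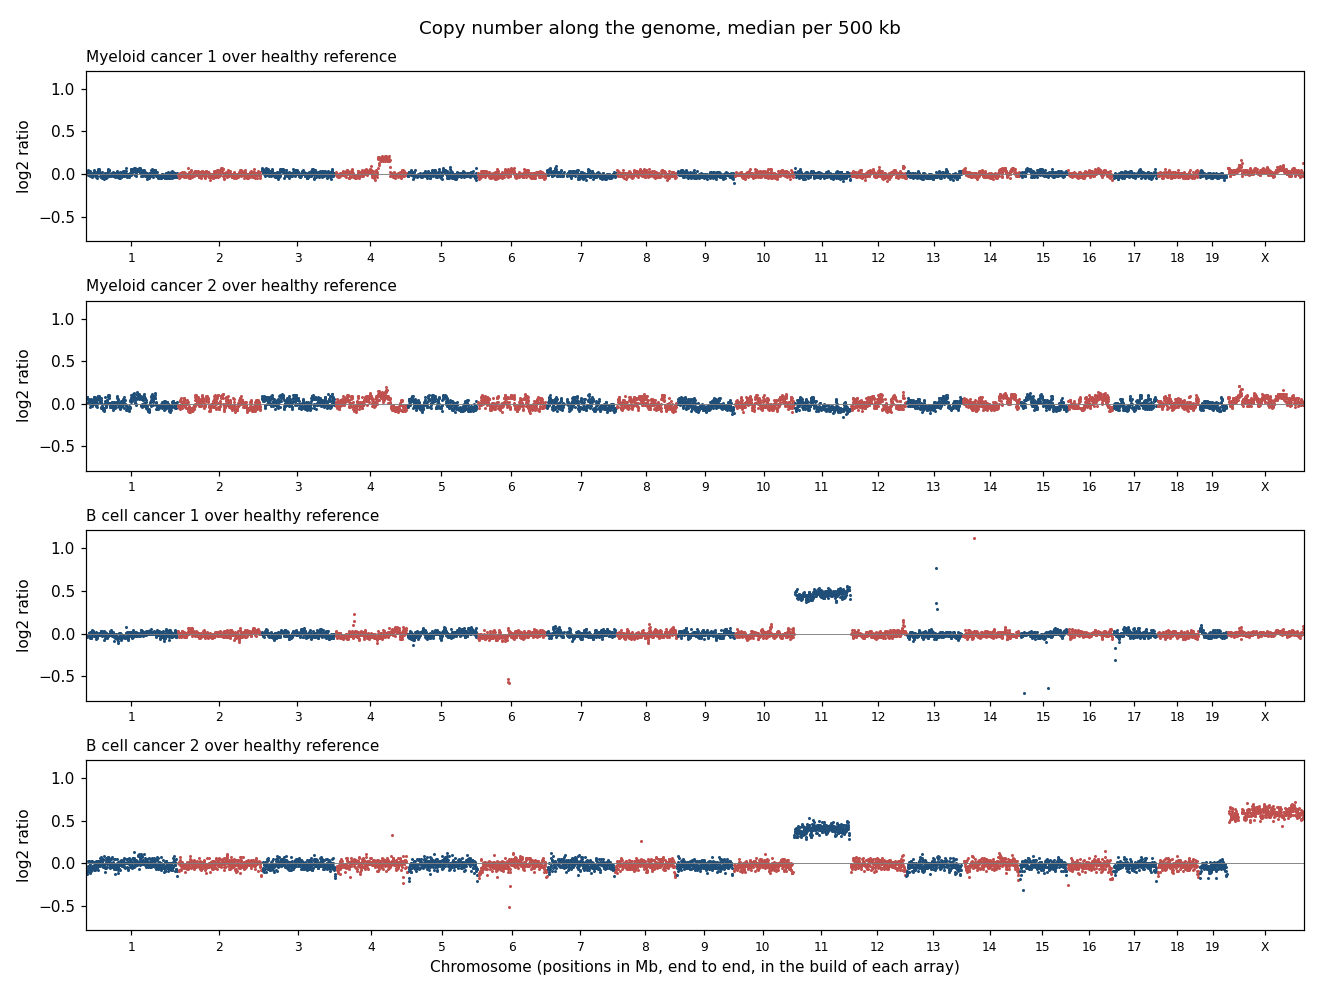
Median log2 ratio of cancer over reference (vertical axis) per 500 kb along chromosomes 1 to 19 and X (horizontal axis) for the 4 arrays, with colours alternating between chromosomes. Chromosome 11 lies at 0.47 and 0.40 in the B cell cancers and at -0.011 and -0.032 in the myeloid cancers, and X lies at 0.60 in B cell cancer 2.

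Chromosome 11 carries several of the genes fixed beforehand for their roles in leukemia, here placed by chromosome alone with the GRCm38.p6 gene table. Of 20 lymphoid and myeloid transcription factors, 3 lie on it: Ikzf1 and Ikzf3, zinc finger factors of lymphocyte development, and Ebf1, a factor that specifies B cells. Of 20 tumour suppressors, 2 lie on it, Trp53, which encodes p53, and Nf1, a negative regulator of Ras. Of 22 oncogenes, only Meis1, a homeobox cofactor, does. Of 18 reported miR-125b targets, 3 do: Trp53, Ppp2ca, the catalytic subunit of a phosphatase, and Stat3, a signalling transcription factor. Of 13 recombination and repair genes, Brca1 does, and of 6 genes that vary in copy between C57BL/6 substrains, Dock2 does. In all, 10 of 95 listed genes lie on chromosome 11, against 1609 of 21631 protein-coding genes (7.44%), and no test of this share was run. Values at the genes themselves were not analysed here. Irf4, the transcription factor named in the study's title, lies on chromosome 13, whose medians were -0.013, -0.0080, -0.014 and -0.024 in myeloid 1, myeloid 2, B cell 1 and B cell 2.

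The X chromosome stood at 0.60 in B cell cancer 2, with Y at -1.08 and unplaced Y sequence at -1.53. X was at 0.027, 0.043 and 0 in myeloid 1, myeloid 2 and B cell 1, and Y at 0.018, 0.034 and 0.045. The cancer mice were female per the labels, and the sex of the reference animals was not stated there. These values compare the sex chromosomes of different animals and are not read here as changes in the cancer. A male reference animal for B cell cancer 2 would raise X and lower Y in this way, which was not tested. The counts of segments and bins still hold these chromosomes. They include 4 of the 11 called segments of B cell cancer 2, 1 of the 5 of myeloid cancer 1 and 18 of the 105 called myeloid bins. The authors' correction moved Y in all 4 arrays. Before correction the Y medians were 0.39, 0.28 and 0.28 in myeloid 1, myeloid 2 and B cell 1, and -0.62 in B cell 2.

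The second comparison set B cell cancer 1 against the reference. Besides chromosome 11 it had 7 gained and 12 lost autosomal regions, spanning 3.01 Mb and 4.35 Mb. The called segments in them covered 2.58 Mb and 4.05 Mb. Among regions of at least 20 datapoints, the highest gain was on chromosome 14 at 26696171 to 27109046, with a log2 ratio of 1.24 ± 0.15 over 118 datapoints. A shorter gain on chromosome 5 at 110362994 to 110425840 had 1.22 ± 0.54 over 19 datapoints. Before correction it was the higher, with 1.28 against 1.25. Below the datapoint minimum, a gain of 5 datapoints on chromosome 12 at 42022457 had 1.56 ± 1.48. A further gain on chromosome 14 at 69873924 to 70087606 had 0.80 ± 0.12. One on chromosome 13 at 65767854 to 66970056 had 0.80 ± 0.48 over its 4 called segments. A gain spanning 1006 kb on chromosome 4 at 41759075 to 42765007 had 0.30 ± 0.15 over its 2 called segments. Losses with the lowest means among regions of at least 20 datapoints lay on chromosome 12 at 114669070 to 114834633 (-1.12 ± 0.92) and on chromosome 5 at 14904582 to 15219512 (-1.08 ± 0.41). By their medians, -0.73 and -1.10, the chromosome 5 loss was the lower. The longest loss was on chromosome 6 at 68257255 to 70022598, spanning 1765 kb, with -0.57 ± 0.21 over the 404 datapoints of its 2 called segments. On chromosome 15, 3 losses had -0.67 ± 0.18 at 9461847 to 10068544, -0.72 ± 0.16 at 59267246 to 59478244 and -0.69 ± 0.15 at 63074897 to 63444096. A loss on chromosome 17 at 6228664 to 6819268 had -0.53 ± 0.29.

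Among segments of at least 10 datapoints, the loss of B cell cancer 1 with the lowest mean lay on chromosome 13 at 30817918 to 30850910. Its 10 datapoints over 33.0 kb had a log2 ratio of -2.92 ± 0.81 and ran from -4.21 to -1.84. By medians, -2.74 and -2.78, a loss of 9 datapoints on chromosome 6 at 70674113 was the lower. The myeloid cancers had -0.039 ± 0.17 and 0.021 ± 0.15 over the chromosome 13 loss. The 100 kb bin that holds it was lower in B cell cancer 1 than in the reference, with an adjusted p of 2.64e-185 in the limma fit, and differed from the myeloid mean by -0.97 ± 0.042 (SE, adjusted p = 4.48e-117 in limma). B cell cancer 2 also had a loss on chromosome 13. In the coordinates of its own build it lay at 30670931 to 30762871, with -0.82 ± 0.51 over 17 datapoints and a lowest datapoint of -2.47. Whether both losses cover the same sequence was not tested, since the builds differ.

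**Figure D2:**
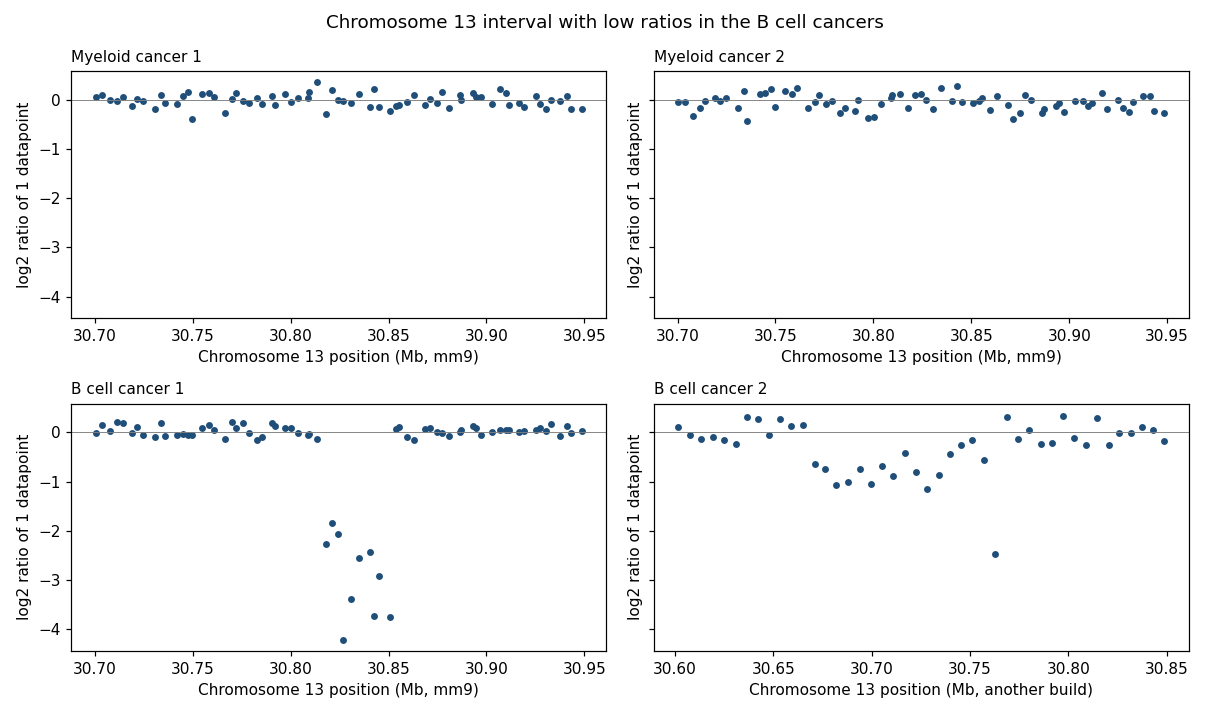
Log2 ratio of single datapoints (vertical axis) along part of chromosome 13 (horizontal axis, Mb) in the 4 arrays, in mm9 for all but B cell cancer 2, whose window is in another build. Datapoints of B cell cancer 1 fall to -4.21, those of B cell cancer 2 to -2.47 within the called loss, and the myeloid means over the B cell cancer 1 interval are -0.039 and 0.021.

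B cell cancer 2 had 5 lost autosomal regions and 0 gained ones besides chromosome 11, spanning 1.73 Mb, with 1.30 Mb in called segments. They lay on chromosomes 6, 12, 13, 15 and 19, and B cell cancer 1 had called losses on the first 4 of these. The loss on chromosome 6 spanned 69040525 to 70046632, with an uncalled gap, and had -0.71 ± 0.38 over the 67 datapoints of its 2 called segments. The loss on chromosome 12 was at 113878867 to 114108939 with -0.71 ± 0.60 over 31 datapoints, and with -0.46 before the authors' correction. The loss on chromosome 15 was at 9476132 to 9729031 with -0.60 ± 0.25, and that on chromosome 19 at 37294735 to 37444269 with -0.37 ± 0.17. Positions in the 2 B cell cancers are of different builds and no overlap was computed.

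Over 25632 bins of 100 kb, limma called 1298 bins in B cell cancer 1 against the reference, 1244 higher and 54 lower. All 1189 bins on chromosome 11 were among the higher ones. The other 109 called bins were 55 higher and 54 lower, and all called bins formed 46 runs. The smallest adjusted p, 1.65e-301, was on chromosome 14 at 26700001 to 27200000, with a mean of 1.03 over 5 bins and an SE of 0.034. These p-values rest on the spread between the myeloid arrays, since B cell cancer 1 is a single array here.

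The third comparison set the myeloid cancers against the reference. The main feature, found in myeloid cancer 1, was a higher ratio over part of chromosome 4, from 94268054 to 120748830 (26.5 Mb, 7342 datapoints). Its mean was 0.18 in myeloid cancer 1 and 0.085 in myeloid cancer 2, and -0.0091 in B cell cancer 1. The interval exceeded the rest of chromosome 4 by 0.18 in myeloid 1 and 0.089 in myeloid 2, and differed from it by -0.0017 in B cell 1. It was below the calling threshold of 0.25. At a threshold of 0.15 it was called in myeloid cancer 1 as 2 segments. It was not called in myeloid cancer 2 at either threshold. The level in myeloid cancer 2 was uneven. Its medians per 500 kb fell to 0.0055 inside the interval, from 117000001, and reached 0.1245 outside it, from 76500001.

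**Figure D3:**
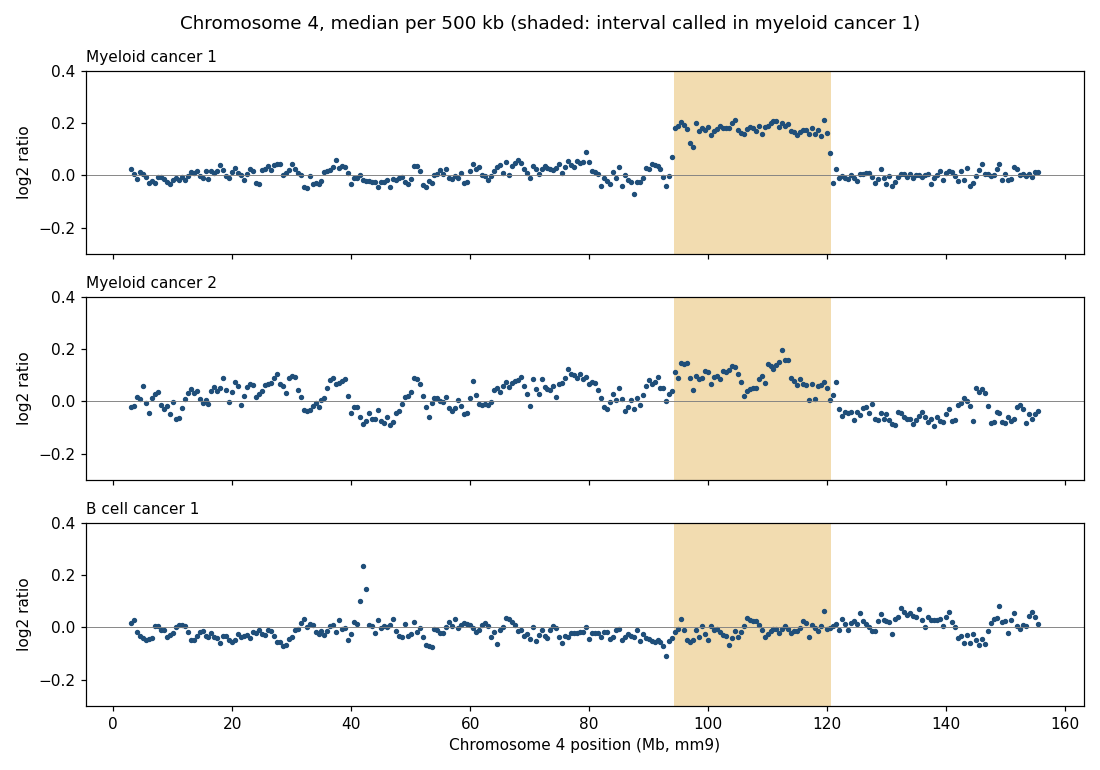
Median log2 ratio per 500 kb (vertical axis) along chromosome 4 (horizontal axis, Mb, mm9) in both myeloid cancers and B cell cancer 1, with the interval from 94268054 to 120748830 shaded. The interval has a mean of 0.18 in myeloid cancer 1, 0.085 in myeloid cancer 2 and -0.0091 in B cell cancer 1.

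Limma called 105 bins in the myeloid cancers against the reference, 98 higher and 7 lower. Of the 98 higher bins, 77 lay in the chromosome 4 interval, which holds 264 bins, and 17 on X. The interval was chosen in an array that enters the myeloid mean, so these 77 bins are no independent support for it. The run of 15 bins at 112500001 to 114000000 on chromosome 4 averaged 0.18, with 0.20 and 0.16 in the 2 arrays and a smallest adjusted p of 2.76e-15. Because this run lies inside the interval, the same limit holds for its p. Centring on the mode gave 62 higher and 10 lower bins. With no minimum size the count rose to 3194 bins (1800 higher, 1394 lower), and after subtraction of a 10 Mb running median it fell to 16. That subtraction removes broad changes by its construction.

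Called segments in the myeloid cancers were few and short. There were 5 in myeloid cancer 1 (2 gains, 3 losses) and 3 in myeloid cancer 2 (0 gains, 3 losses), covering at most 0.325 Mb of loss per array. The deepest was a loss on chromosome 3 at 44434265 to 44468493 with the same ends in both, at -1.67 ± 0.70 and -1.68 ± 0.65 over 11 datapoints, while B cell cancer 1 had 0.015 ± 0.13. The bin that holds it had the smallest adjusted p of the myeloid comparison, 2.71e-170 in limma, at -0.68 ± 0.024 (SE), lower in 2 of 2 arrays. A loss on chromosome 8 at 116306672 to 116323887, with 6 datapoints below the minimum of 10, had -2.49 ± 0.64 and -2.37 ± 0.72. A loss near 106 Mb on chromosome 11 was shallow, at -0.25 ± 0.16 from 106474776 to 106642195 in myeloid cancer 1 and -0.27 ± 0.16 from 106460595 to 106688167 in myeloid cancer 2. This call sits at the threshold of 0.25. The median of datapoints in myeloid cancer 1 was -0.23, and after subtraction of a 10 Mb running median the means were -0.23 and -0.21, all short of it. On X, the segment at 30750855 to 30850547 had 0.39 ± 0.20 in myeloid cancer 1 and 0.33 ± 0.22 in myeloid cancer 2, where it was not called, and 0.22 ± 0.20 in B cell cancer 1, which has the same reference DNA.

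The fourth comparison was between the lineages, with B cell cancer 1 set against the myeloid mean. Limma called 1429 bins, 1241 higher and 188 lower in B cell cancer 1. Of the higher bins, 1188 lay on chromosome 11, and of the lower bins, 117 lay in the chromosome 4 interval. That interval was chosen in myeloid cancer 1, which enters the myeloid mean, so these 117 bins are no independent support for it. The run over chromosome 11 from 3100001 to 121900000 had a mean difference of 0.49. The top runs included the gains on chromosomes 13 and 14 and the losses on chromosomes 5, 6, 12 and 13 given above, with run means from -0.97 to 1.05 off chromosome X. The single bin on X at 166400001 to 166500000 differed by 1.08 ± 0.042 (SE). It stood at 0.87 in B cell cancer 1 and at -0.13 and -0.28 in the myeloid cancers.

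Averaged over the lineages, limma called 1255 bins in the 3 arrays, 1207 higher and 48 lower, with 1179 of the higher bins on chromosome 11. This average gives B cell cancer 1 as much weight as the myeloid pair. All of its 10 runs with the smallest adjusted p had a larger absolute value in B cell cancer 1 than in either myeloid cancer. On chromosome 14 at 26700001 to 27100000 the values were -0.0039, -0.052 and 1.24 in myeloid 1, myeloid 2 and B cell 1.

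All 3 segments of myeloid cancer 2 recurred among the 5 of myeloid cancer 1, against a highest count of 0 in 1000 random shifts. Of these 3, the loss near 106 Mb on chromosome 11 rests on the threshold, as given above. Myeloid cancer 1 and B cell cancer 1 shared 2, and myeloid cancer 2 and B cell cancer 1 shared 1, each against at most 1 after shifting. B cell cancer 1 had 25 called segments. The loss on chromosome 6 at 115899477 to 115962445 was called in all 3 arrays, at -0.46 ± 0.13, -0.56 ± 0.20 and -0.47 ± 0.090 in myeloid 1, myeloid 2 and B cell 1. The gain on chromosome 6 at 47081697 to 47118013 had 0.50 ± 0.25, 0.58 ± 0.27 and 0.60 ± 0.16, and was called in myeloid 1 and B cell 1. These arrays share 1 reference DNA, and a difference in that DNA would appear in all 3. The random shifts place segments independently, so they do not separate changes in the cancer from such a difference. Variants carried by the mice from birth were not separated either, because normal DNA of the same mice was not analysed here.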

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

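All tests in this part were chosen after the results were seen, except those for a slow wave on chromosome 4 and for a distant mouse strain, whose predictions were written before their values were known.

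Chromosome 11 stood out because its median differed between the lineages, by 0.45 (log2, B cell minus myeloid). The authors' normalization as the whole cause is argued against by the uncorrected ratios, whose smaller B cell median was 0.35, and GC content by a smaller B cell median of 0.40 after a GC correction. For B cell cancer 1 the reference DNA is argued against too, since the higher median of the myeloid arrays on that reference was -0.011. For B cell cancer 2 a difference in its reference DNA cannot be told apart from a gain, because 0 other arrays used that reference. Organ and array design are argued against for B cell cancer 1, which shared both with the myeloid arrays and stood at 0.47. An extra chromosome 11 in most cells of the B cell cancers is a hypothesis that stays open and was not tested.

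Chromosome 4 stood out because its median also differed between the lineages, by -0.032, with a higher mean in both myeloid arrays over 26.5 Mb. A difference in the shared reference DNA is argued against for the level of the whole interval by B cell cancer 1, in which the interval minus the rest of the chromosome was -0.0017, and GC content by the smaller myeloid difference after correction, 0.089. The interval was found in myeloid cancer 1 itself, so its step there tests nothing, and a gain in a minority of the cells of that sample is an untested hypothesis. In myeloid cancer 2 the step at the same edges, 0.070, lay at percentile 98.85 of 10000 random intervals, between the bounds set beforehand, and B cell cancer 1, whose interval was not raised, had a step of 0.041 there at percentile 98.4, so a slow wave along the chromosome cannot be told apart from a gain in a part of the cells of myeloid cancer 2. The interval of myeloid cancer 2 exceeded the rest of the chromosome by 0.089, more than the highest random interval (0.077), but random intervals of this length overlap one another heavily.

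Besides chromosome 11, B cell cancer 1 had 17 focal regions (6 gains, 11 losses, spanning 7.26 Mb) past the threshold in neither myeloid array, with a median size of 0.69. A difference in the shared reference DNA is argued against as the main cause of all 19 regions called there, since their median myeloid value, signed by the direction in B cell cancer 1, was -0.0021, but it stays open for the 2 that were past the threshold in a myeloid array. Stretches from a distant mouse strain may raise such differences and would also leave isolated low datapoints. Their number in B cell cancer 1 was 1.55 times the myeloid mean (51 against 25 and 41), between the bounds set beforehand, and 5.88% of them (3 of 51) lay within 2 Mb of these regions, against 2.95% of all datapoints, so this explanation cannot be told apart. Changes that arose in the cancer and variants carried by the mouse from birth were not separated, because normal DNA of the same mouse was not analysed here.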

How the results depend on the processing

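The gain of chromosome 11 in the B cell cancers held under each of the following settings. Its mean ranged from 0.41 to 0.43 with the mean of datapoints, without centring, before correction or after GC correction. Without centring or correction, with the mean of datapoints or with GC correction, the lineage difference stayed between 0.43 and 0.46, and with each array left out in turn between 0.42 and 0.49, always with chromosome 11 as the 1 autosome changed by at least 0.15.

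Total counts of bins moved by over 1.5 times under 3 settings. With 500 kb bins, 5 times as wide, they were 251 for the average over the lineages, 14 for myeloid, 261 for B cell 1 and 284 for B cell 1 minus myeloid. Without a minimum size they were 2484 for the average and 3194 for myeloid. After subtraction of a 10 Mb running median, which removes chromosome 11 and the chromosome 4 interval by construction, they were 73, 16, 107 and 110. The ratio before correction gave 85 higher and 18 lower myeloid bins, and centring on the mode 62 and 10, against 98 and 7. Without a minimum size, lower bins rose from 54 to 116 for B cell 1 and from 188 to 348 for its difference from myeloid. Lower bins of that difference were 128 with centring on the mode and 261 without centring. Without B cell cancer 1 the myeloid count stays 105 by construction, since a lone array adds nothing to the myeloid means or spread, so this tests nothing. Other left-out arrays leave no residual degrees of freedom, and those alternatives gave no test.

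Called segments moved most in the myeloid arrays, where counts are small. Myeloid 1 had 5, and 9 at a threshold of 0.15, 3 at 0.4, 0 with at least 50 datapoints, 2 with the running median over 50, 8 with at least 5 datapoints, 3 with a penalty of 8 log n and 8 before correction. Myeloid 2 had 3, and 1 with at least 50 datapoints, 1 with the running median and 7 with at least 5 datapoints. B cell 1 had 25, and 12 with at least 50 datapoints and 15 with the running median. B cell 2 had 11, and 5 with at least 50 datapoints. The cause of these shifts was not tested beyond the settings' own limits. Shared segments changed by at most 1 with the overlap rule, from 3 to 2 between the myeloid arrays. The 10 Mb running median left 4 regions over 5 Mb long near 0 by construction, with -0.0012 for chromosome 11 in B cell 1, a change of sign, 9.43e-06 for chromosome 11 and 0.0023 for X in B cell 2, and -0.050 for its unplaced Y sequence, and gave no value for 1 region, on Y. Over 37 called regions, the other 180 alternative values held 0 changes of direction, and ranged from 0.579 to 1.30 times the main value, with the extremes on Y and X in B cell 2 before correction. Among autosomal regions of these 180 values, the chromosome 12 loss at 114669070 in B cell 1 moved by over 1.5 times, to a median of -0.73. The chromosome 12 loss of B cell 2 also did, to -0.46 before correction.

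Planned locus values for Irf4, the antigen receptor loci, the gene lists and the miR-125b hairpins were not run, since gene positions in these builds were not used here. No paired analysis was run, because a myeloid and a B cell sample share only the number 1.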

Other observations

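All tests in this part were chosen after the results were seen. Both B cell cancers had focal losses on chromosomes 6, 12, 13 and 15, each given in the build of its array. On chromosome 6, a short and deep loss lay beyond the long one in both. It was at 70674113 to 70700999 in B cell cancer 1, with -2.90 ± 0.65 over 9 datapoints, and at 70656219 to 70679019 in B cell cancer 2, with -2.31 ± 1.02 over 5 datapoints. Shallow and deep parts also lay within 1 loss on chromosome 12, where datapoints of B cell cancer 1 ran from -3.29 to -0.096. The deepest datapoints lie below the nominal -1 of a single lost copy.

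The chromosome 6 and 12 losses may reflect antigen receptor DNA removed during B cell development, since the immunoglobulin kappa and heavy chain loci lie on these chromosomes in the mouse. The prediction, that the intervals lie inside these loci in the build of each array, could not be tested with the gene table used here. The myeloid arrays were slightly high over the chromosome 12 loss of B cell cancer 1, with 0.12 in myeloid cancer 1 and 0.12 in myeloid cancer 2. A reference DNA that itself holds some rearranged lymphocytes would give such a sign, and this was not tested.

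The chromosome 13 losses may include Irf4, the gene named in the study's title, which lies on that chromosome. The value of -2.92 in B cell cancer 1 shows a deep loss, and whether it overlaps Irf4 was not tested, since gene positions in these builds were not used here. Myeloid cancers 1 and 2 had -0.039 and 0.021 over the interval of B cell cancer 1.

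Between the myeloid arrays, bins on autosomes other than 11 and outside called regions correlated with r = 0.568 across 22717 bins, against 0.258 between myeloid 1 and B cell 1 and -0.0602 between myeloid 2 and B cell 1. Bins are not independent replicates. All 3 arrays share 1 reference DNA, which by itself raises such correlations, and the value without any shared change was not computed, so r is not read as shared change. The labels give the number 1 to a myeloid and a B cell sample. Those samples differed in the chromosome 3 loss, with -1.67 and 0.015, and over the chromosome 14 gain at 26696171, with -0.0033 and 1.24.

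Short called segments below the datapoint minimum recurred in both myeloid arrays on chromosome 13 at 120268745 to 120284228 (-0.47 ± 0.43 and -0.47 ± 0.50, with -0.28 ± 0.37 in B cell cancer 1) and on X at 166402816 to 166417556 (-0.82 ± 0.68 and -0.74 ± 0.60). On X, B cell cancer 1 had a gain of 1.49 ± 1.00 at 166410784 to 166435099, in part over the same sequence. Of the list of genes that vary in copy between C57BL/6 substrains, Ide and Fgfbp3 lie on chromosome 19, where B cell cancer 2 had its loss of -0.37, and their overlap with it was not tested. Across the 3 arrays of 1 design, 0 datapoints exceeded 0.9 in all arrays and 4 were below -0.9 in all.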
